A study of Mus musculus with 2 samples.

How the data were processed

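The data were 2 single-cell RNA sequencing libraries from mouse cerebellum at postnatal day 1 (P1), 1 from Cxcr4+/+ mice (control) and 1 from Cxcr4+/1013 mice (mutant). Per the labels' protocols, lobules III-IV were microdissected in ice-cold buffer, dissociated with papain and carried through droplet capture and 3' library preparation with 10X Genomics v3.1 chemistry. The genotype and title labels give the mutant as Cxcr4+/1013, whereas the wording of the extraction protocol gives Cxcr4+/-. The genotype label was used here. The number of animals behind each library is not given in the sources used here.

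Reads were processed with bcl2fastq 2.20.0.4222 and Cell Ranger 7.2 against mm10, per the submitters' processing notes, and Cell Ranger is also named in the matrix headers. Whether intronic reads were counted, and which annotation release was used, is not given in the sources used here. The deposited matrices held raw counts, that is, whole-number counts of unique molecular identifiers (UMIs) for each gene and cell barcode, with no normalisation. The other deposited files, the barcode and feature lists, held no measurement and gave the names of the matrix columns and the identifier and symbol of each of 32285 genes, identical in both libraries. The matrices held only barcodes with at least 500 UMIs, so that droplets with fewer UMIs were not part of them and free RNA could not be measured from them directly. Whether some of the barcodes held were empty droplets was not tested.

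The control library held 9586 barcodes with 120003656 UMIs, a median of 11028.5 UMIs and 3984 genes per barcode, and a median of 3.30% mitochondrial UMIs. The mutant library held 9551 barcodes with 130429500 UMIs, a median of 12332 UMIs and 4270 genes per barcode, and a median of 2.97% mitochondrial UMIs. Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, which left 8353 control and 8194 mutant barcodes. Doublets were scored in each library with Scrublet in scanpy 1.11.5, and the highest scores were removed at a rate of 0.8% per 1000 deposited barcodes, that is 7.67% of the control and 7.64% of the mutant barcodes. Scrublet's own threshold would have taken 442 control barcodes (5.29%) and 353 mutant barcodes (4.31%). After this step 7712 control and 7568 mutant cells were retained, with a median of 11905 and 13280 UMIs.

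Both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with the library as batch and without mitochondrial, ribosomal protein, haemoglobin and sex-linked genes, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 38 clusters. Clusters were named from 20 fixed lists of marker genes. A marker counted as enriched when it was detected in at least 10% of a cluster's cells and was at least 2-fold above its level in the other clusters, and a name needed at least 3 enriched markers. Clusters with a median depth under 0.333 of the library median and none of their own markers among their 10 leading genes stayed unnamed. So did clusters of other classes with midbrain or brainstem neuron markers enriched and among their leading genes. A cluster with more markers of another candidate class among its leading genes took the name of that class. The marker lists were fixed before the data were examined, and these naming thresholds were set after that. A name such as granule neuron-like therefore says which marker list a cluster carried.

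With 1 library per genotype there were no replicates, and cells were not used as replicates. No test was run, no p-value or standard error was computed, and every difference is one between 2 libraries. Shares of cells carry exact Clopper-Pearson 95% intervals, apart from shares of 0, which carry the limit that 3 counts would give, summed UMIs carry exact Poisson 95% intervals, and ratios of summed UMIs or of cell numbers carry exact conditional binomial 95% intervals. These intervals cover counting error only and not the difference between animals, dissections or preparations. UMIs were summed over the cells of a class and scaled to the total UMIs of that class as CPM, the usual scale of summed counts. Genes with at least 50 UMIs over both libraries were counted as higher or lower when they differed at least 1.5-fold, as a description by size, in the whole library and in the classes with at least 100 cells in each library. Granule cell progenitors, granule neurons, Purkinje cells and astroglia or Bergmann glia were the main classes. For a gene with 0 UMIs in 1 library the fold is a lower bound from a floor of 3 counts over that library.

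The named genes followed a fixed rule. In the whole library and in each main class these were the 8 genes higher and the 8 lower in the mutant library whose ratio interval had its bound nearest to 1 farthest from 1, without sex-linked, mitochondrial, ribosomal protein and haemoglobin genes and predicted gene models. To these were added 4 members of each gene list outside the 2.5th to 97.5th percentile in a main class, 2 genes per direction in the other classes, and a fixed set with Cxcr4, Cxcl12, Ackr3, Atoh1, Neurod1, Gli1, Ptch1, Ccnd1, Ccnd2, Mycn, Mki67, Shh, Xist and the Y-linked genes.

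The 19 gene lists were the CXCL12-CXCR4 axis, the Sonic hedgehog pathway, S phase, G2/M phase, granule neuron differentiation, migration and axon guidance, the Notch pathway, Wnt pathway targets, BMP and TGF-beta targets, synaptic and neuronal maturation, Purkinje cell maturation and zones, immediate early and dissociation, hypoxia and glycolysis, interferon response, p53 and apoptosis, cytosolic ribosomal proteins, mitochondrially encoded genes, sex-linked genes and the neighbours of Cxcr4 on chromosome 1. Members with at least 20 UMIs over both libraries entered a list's median log2 ratio, with a count of 0.5 in place of 0, and at least 5 such members were needed. Each median was placed as a percentile among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these 2 libraries and is no test of the genotype.

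Shares of cells with at least 1 UMI of a gene were measured after every cell was thinned at random to 2000 UMIs, and shallower cells were left out. This kept 6882 of 7712 control cells (89.2%) and 7246 of 7568 mutant cells (95.7%). Because a single thinning draw moved some of these shares, the average expected over all draws was added after the data were seen and is named as such. It and its standard deviation over draws were calculated from each cell's probability of keeping a UMI, without repeated draws. The other thinned shares are of a single draw. Cells were called female with at least 3 Xist UMIs and at most 1 Y-linked UMI, and male with at least 2 Y-linked UMIs and at most 2 Xist UMIs, thresholds also set after the data were seen.

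The cell classes, gene lists, thresholds, rule for named genes and 68 alternatives were chosen before the data were examined, apart from the choices named above as later. The alternatives covered the barcode filter (a stricter one with at least 1000 genes and at most 5% mitochondrial UMIs, and none), doublet removal, clustering resolution, cell cycle genes, centring of genes within each library, thinning, the minimum count, the fold size, genes with most of their RNA in another class, TMM factors from edgeR 4.0.16 and size factors from DESeq2 1.42.0. A further 22 alternatives were chosen after seeing the data and covered cells of each sex, low-depth clusters named by their markers alone, genes with most of their UMIs in 1 cell, and the average over thinning draws. GC content and exon counts came from GENCODE M21 on GRCm38, and 99.6% of the listed genes had a GC value. The procedure was tested on simulated data drawn from the pooled counts of both libraries, in which a 2-fold difference was recovered for 91.0% to 98.5% of the altered genes and a 1.5-fold difference for 37.3% to 56.7%, while 1.07% to 1.67% of the unaltered genes reached the fold size. The simulated counts held Poisson counting error only. They therefore do not measure the error that animals or preparations add between unreplicated libraries. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and in R 4.3.3.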

Results

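Single-cell transcriptomes were collected from lobules III-IV of the mouse cerebellum at P1, in 1 library from Cxcr4+/+ mice and 1 from Cxcr4+/1013 mice. The 1013 allele encodes a CXCR4 receptor with a truncated C-terminal tail, the kind of change that causes a dominantly inherited immunodeficiency in humans, and the series title asks about neurodevelopmental origins of disease in this setting. At this age granule cell progenitors divide in the external granule layer, where CXCL12 from the meninges holds CXCR4-expressing progenitors near the surface. The comparison therefore asked how the cell types of the lobules, the granule lineage in particular, and their transcripts differed between the genotypes. The control library gave 120003656 UMIs from 9586 barcodes and the mutant library 130429500 UMIs from 9551 barcodes. After filtering and doublet removal 7712 control and 7568 mutant cells remained, with 101040947 and 110919099 UMIs. There was 1 library per genotype and no replicate, so values are set side by side with intervals for counting error.

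Neuronal classes of the granule and interneuron lineages made up more of the mutant library, and astroglial, vascular and meningeal classes made up less of it. Granule neuron-like cells were 13.8% of control cells (95% interval 12.996% to 14.5%) and 18.4% of mutant cells (17.5% to 19.3%), a ratio of 1.34. GABAergic interneuron-like cells, marked by Gad1 and Gad2, and by Pax2 in all but clusters 22 and 32, were 16.0% of control and 21.6% of mutant cells, a ratio of 1.35. Astroglia or Bergmann glia-like cells were 9.74% (9.09% to 10.4%) and 6.20% (5.66% to 6.76%), a ratio of 0.636. Among the named neural cells, which leave out vascular, meningeal, immune and unnamed cells, the ratios were 1.20 for granule neuron-like, 1.21 for GABAergic interneuron-like and 0.572 for astroglia-like cells. Meningeal or vascular fibroblast-like cells, a main source of CXCL12, numbered 170 in the control and 33 in the mutant library, that is 2.204% (1.89% to 2.56%) and 0.436% (0.300% to 0.612%).

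Granule cell progenitor-like cells were 17.4% (16.5% to 18.2%) of control and 19.5% (18.6% to 20.4%) of mutant cells, but 21.2% (20.2% to 22.2%) and 21.3% (20.4% to 22.3%) of the named neural cells. Unipolar brush cell or rhombic lip-like cells were 5.41% and 7.11%, and GABAergic or glial progenitor-like cells were 2.84% and 4.08%. Purkinje cell-like cells were 6.76% and 5.72%, a ratio of 0.847 (0.744 to 0.964), or 0.762 among the named neural cells. Their main cluster 5 held 421 and 397 cells. Most of the difference lay in clusters of lower median depth, cluster 29 (84 and 31 cells, 4414 UMIs) and cluster 36 (16 and 5 cells, 1609 UMIs). Cells with markers of glutamatergic cerebellar nuclei were 5.54% and 4.78%. Their cluster carried Lhx9, Lhx2, Meis2 and Slc17a6 without enrichment of Tbr1. Its leading genes included Tfap2d, Tcf7l2 and Shox2, which midbrain neurons also carry, so a cerebellar origin of these cells was not established. Endothelial-like cells were 1.09% and 0.502%, mural-like cells 0.648% and 0.317%, and ependymal-like cells 2.54% and 1.78%. Oligodendrocyte lineage-like cells were 2.04% and 2.06%, microglia-like cells 0.584% and 0.449%, and border macrophage-like cells 0.337% and 0.423%, differences not detectable at this depth over all retained cells. Lymphocyte or granulocyte-like cells numbered 11 and 5.

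Unnamed clusters held 12.993% of control and 6.65% of mutant cells. Cluster 14 (4.42% and 1.31%) and cluster 19 (3.94% and 0.832%) had low depth, with medians of 2395 and 1672 UMIs. Markers alone would call cluster 14 granule neurons, from Rbfox3, Grin2b and Reln, and cluster 19 astroglia, from 8 markers. Cluster 23, led by Hbb-bs, held 1.09% and 2.06% of cells at a median of 746 UMIs. Cluster 13 (3.54% and 2.44%) was led by Gata3, Six3, Tal1, Sox14 and Otx2, transcription factors of midbrain and diencephalic neurons. With the low-depth clusters named by their markers, the granule neuron-like share was higher in the mutant library by 1.51 points, against 4.62, and the astroglia-like difference was -6.65 points, against -3.54. The progenitor-like share was higher by 2.07 points, but by 0.945 under a stricter barcode filter, and the Purkinje-like difference of -1.03 points turned to 0.271 when doublet removal was doubled.

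**Figure D1:**
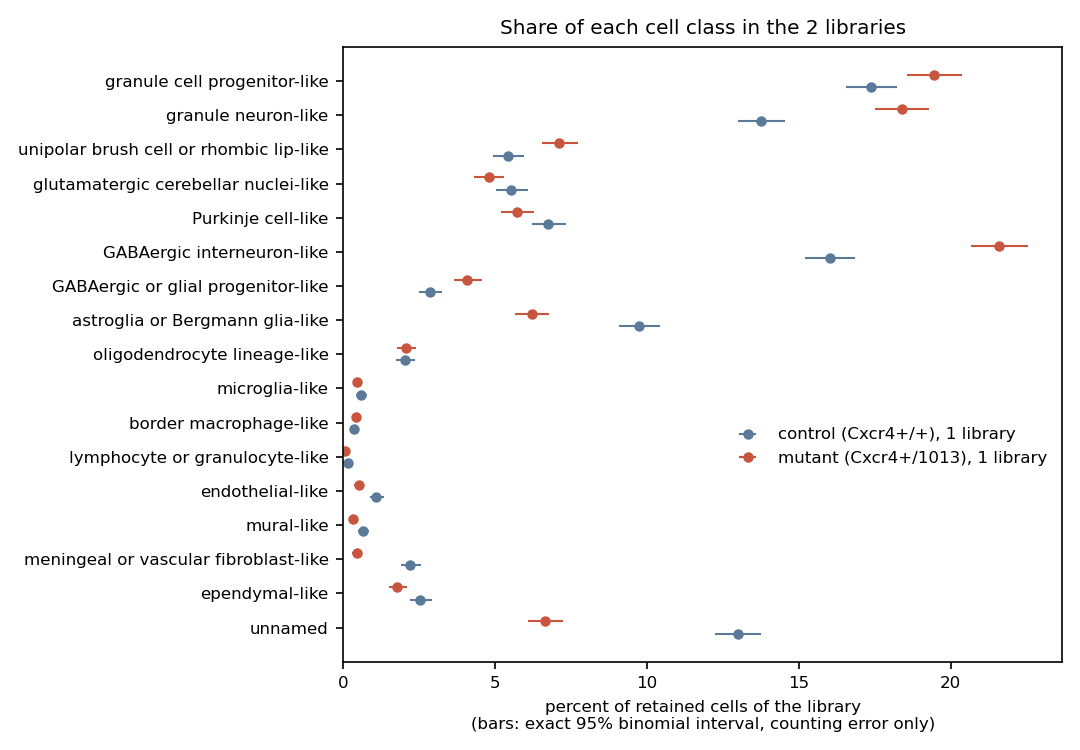
Percent of retained cells (x axis) in each cell class (y axis) for the control and mutant libraries, with points for the shares and bars for exact 95% binomial intervals. Granule neuron-like cells were 13.8% and 18.4%, and astroglia-like cells 9.74% and 6.20%, of control and mutant cells.

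Each library held cells of both sexes, read from Xist and from Y-linked genes. Female cells were 44.6% of control and 44.1% of mutant cells, male cells were 32.7% and 41.8%, and the others were unassigned. Fibroblast-like and astroglia-like cells were a smaller share of the mutant library in both sexes. The fibroblast-like ratio was 0.184 (0.0986 to 0.321) among female and 0.174 (0.0847 to 0.328) among male cells. The vascular classes were lower beyond counting error among female cells only, with an endothelial-like ratio of 0.284 (0.112 to 0.637) and 0.503 (0.223 to 1.09) and a mural-like ratio of 0.215 (0.0640 to 0.574) and 0.796 (0.313 to 2.02) among female and male cells. Oligodendrocyte lineage-like cells had a ratio of 0.641 (0.433 to 0.938) among female and 1.16 (0.814 to 1.68) among male cells. Most of the 45 control and 34 mutant microglia-like cells, with median depths of 2096 and 1930.5 UMIs, were unassigned. Microglia-like cells numbered 9 and 1 among female cells, a ratio of 0.115 (0.00261 to 0.826), and 2 and 8 among male cells, 3.18 (0.635 to 30.8). Astroglia-like cells were 10.8% of control and 6.78% of mutant female cells, and 12.6% and 6.83% of male cells. Granule neuron-like cells were 15.1% and 17.1% of female cells and 15.1% and 21.3% of male cells. Progenitor-like cells were 18.5% and 18.3% of female cells and 22.8% and 23.2% of male cells, differences within counting error. Because more control than mutant cells were left out as unassigned, these values do not decide whether the higher progenitor share held within each sex. Cells with markers of cerebellar nuclei were a larger share of the mutant library among female cells, with 7.16% and 9.72%, and a smaller share among male cells, with 3.38% and 0.632%. The midbrain-like cluster 13 was also a smaller share among male cells, with 2.30% and 0.632%, and held 4.02% and 4.53% of female cells.

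**Figure D2:**
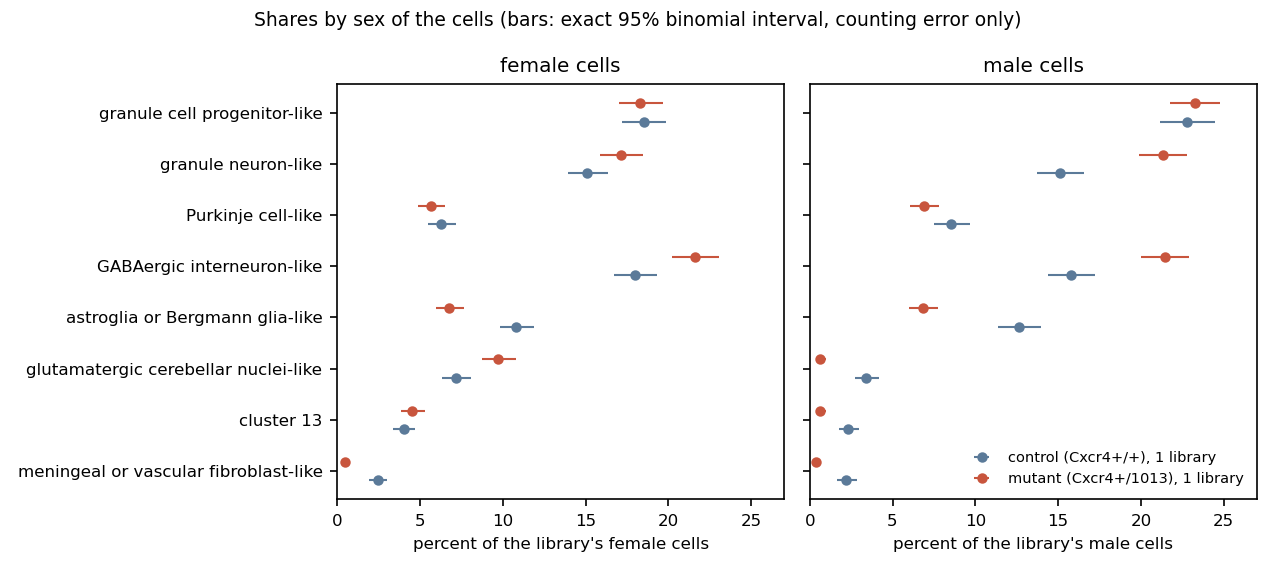
Percent of female cells (left panel) and of male cells (right panel) in 8 classes and clusters for the control and mutant libraries, with points for the shares and bars for exact 95% binomial intervals. Cells with markers of cerebellar nuclei were 7.16% and 9.72% of female cells and 3.38% and 0.632% of male cells.

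Within the granule lineage, the balance lay further toward neurons in the mutant library. Progenitor-like cells were 55.8% (53.8% to 57.8%) of the lineage in the control and 51.4% (49.6% to 53.3%) in the mutant library, a difference of -4.40 points. The difference was -3.41 points among female cells and -8.00 points among male cells. It turned when clustering was coarser, to 1.02 points, and when the low-depth cluster with granule neuron markers was counted with the neurons, to 0.827 points.

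The S phase and G2/M phase transcripts of progenitor-like cells lay close together in the libraries. Summed S phase genes, which serve DNA replication, stood at 6021 CPM (UMIs of the genes scaled to the total of the class) in the control and 5934 in the mutant library, a ratio of 0.986 (0.978 to 0.993). Summed G2/M genes, which serve mitosis, stood at 13436 and 13874, a ratio of 1.03 (1.03 to 1.04). Over the whole granule lineage, S phase genes stood at 4170 and 3895 and G2/M genes at 9245 and 9040. Mki67, a marker of cycling cells, had a UMI in 552 of 1311 control progenitor-like cells (42.1%, 39.4% to 44.8%) and in 721 of 1465 mutant ones (49.2%, 46.6% to 51.8%) at 2000 UMIs per cell. The average over draws was 43.3% and 47.4%, a difference of 4.05 points that was 5.36 among female and 2.79 among male cells, and without thinning the shares were 81.3% and 83.7%. At 4000 UMIs per cell the average difference was 3.45 points, against 1.23 in the single draw. Top2a, the topoisomerase of dividing cells, had a UMI in 50.6% and 51.5% of progenitor-like cells, with an average over draws of 50.7% and 52.1%. Among female cells the Top2a difference was 0.427 points on average and -1.46 in the single draw. As background, Mki67 was found in 3 of 497 control and 1 of 428 mutant Purkinje cell-like cells, whose median depths were 33565 and 36170 UMIs, against 16226.5 and 17671.5 in progenitor-like cells before thinning.

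Cxcr4 (ENSMUSG00000045382, GRCm38 chromosome 1, 128588199 to 128592293) was transcribed in progenitor-like, astroglia-like and ependymal-like cells, and its ratio of mutant to control differed between classes. In the whole library it stood at 27.8 and 24.2 CPM, a ratio of 0.871 (0.826 to 0.919), and its highest level, 389 and 165, was in lymphocyte or granulocyte-like cells, from 19 and 7 UMIs. In progenitor-like cells it stood at 56.5 CPM (53.4 to 59.7) in the control and 55.1 (52.3 to 58.0) in the mutant library, a ratio of 0.975 (0.904 to 1.05). In astroglia-like cells it was higher in the mutant library, at 80.5 and 104 (ratio 1.30, 1.17 to 1.43), and in ependymal-like cells it stood at 113 and 114. It was lower in the mutant library in granule neuron-like cells, at 4.25 and 2.49 (ratio 0.587, 0.380 to 0.903) or 1.13% of its highest class, in GABAergic or glial progenitor-like cells, at 26.7 and 14.4 (ratio 0.541), and in GABAergic interneuron-like cells, at 2.88 and 1.35 (ratio 0.467). Purkinje cell-like cells, which hold little of this transcript, gave 0.912 and 0.813. The deposited counts are per gene and do not tell the 1013 allele from the wild-type allele.

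Cxcl12 (ENSMUSG00000061353, chromosome 6, 117168535 to 117181367), which encodes the ligand of CXCR4, was far lower in the mutant library as a whole, at 81.4 and 29.8 CPM, a ratio of 0.367 (0.352 to 0.382). Fibroblast-like cells held 6453 of 8221 control UMIs and 1049 of 3310 mutant UMIs, and within this class of 170 and 33 cells the level was 2486 and 2191, a ratio of 0.881 (0.825 to 0.941). In granule neuron-like cells Cxcl12 stood at 101 and 110, a log2 ratio of 0.12 that was -0.08 among male cells, and in endothelial-like cells at 112 and 107. Some classes with little Cxcl12 lay lower in the mutant library, with 6.31 and 1.48 in cells with markers of cerebellar nuclei (ratio 0.234, 0.0790 to 0.579) and 2.43 and 1.35 in GABAergic interneuron-like cells (0.553, 0.331 to 0.917). Astroglia-like cells gave 2.13 and 1.13 (0.533, 0.207 to 1.23) and Purkinje cell-like cells 0.977 and 0.678 (0.694, 0.279 to 1.65). Ackr3 (ENSMUSG00000044337, chromosome 1, 90203980 to 90216751), the scavenging receptor of CXCL12, stood at 72.5 and 85.8 in astroglia-like cells, a log2 ratio of 0.24 that was -0.15 among female and 0.55 among male cells, and at 11.02 and 7.41 in the whole library. The other genes of the CXCL12-CXCR4 axis, G proteins, arrestins and receptor kinases, left the list inside the central 95% of random lists. The median log2 ratio of the axis was 0.15 in progenitor-like cells (percentile 94.6 of random lists), 0.09 in granule neuron-like cells (percentile 80.1), 0.04 in Purkinje cell-like cells (percentile 77.8) and 0.13 in astroglia-like cells (percentile 85.8). The neighbours of Cxcr4 on chromosome 1 had medians of 0.08, 0.06, 0.04 and 0.09 in these classes, at percentiles 58.4, 57.2, 72.1 and 67.9.

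**Figure D3:**
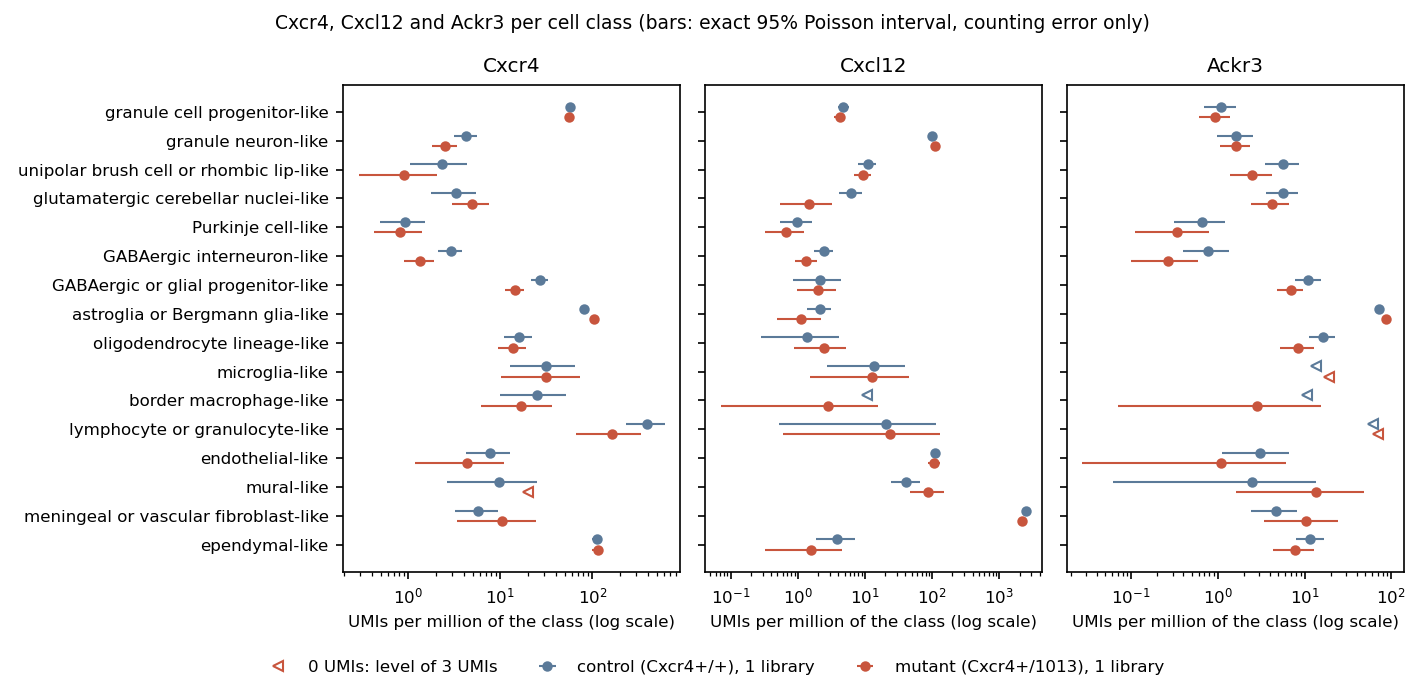
CPM of each cell class (x axis, log scale) for Cxcr4, Cxcl12 and Ackr3 in the control and mutant libraries, with bars for exact 95% Poisson intervals and open triangles for 0 UMIs, drawn at the level of 3 UMIs. Cxcr4 stood at 56.5 and 55.1 in progenitor-like cells, and Cxcl12 at 2486 and 2191 in fibroblast-like cells, in the control and mutant libraries.

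Progenitor-like cells of the mutant library held more transcripts of genes that mark granule neuron differentiation and synapses, and fewer of most ribosomal proteins. Of 13430 genes, 437 were at least 1.5-fold higher and 166 at least 1.5-fold lower in the mutant library, a split that moved from 72.5% higher to 59.5% with TMM factors (333 and 227) and to 60.5% with DESeq2 factors (341 and 223). The genes ranked highest were Jund, an AP-1 transcription factor, at 70.1 and 253 CPM (log2 ratio 1.85, 1.77 to 1.93), C1ql1, a secreted synapse organiser (1.94, 1.76 to 2.13), and Aard (2.03, 1.72 to 2.36). Dapk3, a serine/threonine kinase (2.03), Taf10, a subunit of the general transcription factor TFIID (1.58), Mlycd, the malonyl-CoA decarboxylase (1.81), and Pdxp, a pyridoxal phosphatase (1.57), followed. Actc1, a cardiac actin, also ranked high (2.39), but 61.7% of its mutant UMIs came from 1 cell. The genes ranked lowest were Tnc (-2.46, -3.17 to -1.82), Hes5, a Notch effector (-1.44), Col3a1 (-1.82), Gria1 (-1.31), Gsta4 (-1.43), Sparcl1 (-1.07), Otx2 (-1.44) and Aqp4 (-1.22). These 8 genes stood at 0.0315% to 1.87% of their level in the class with most of them, such as astroglia-like cells for Tnc, Hes5 and Aqp4 and fibroblast-like cells for Col3a1.

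Among the lists in progenitor-like cells, 21 of 23 members of granule neuron differentiation were higher in the mutant library, 17 with an interval above 0, and the median log2 ratio was 0.14 (percentile 98.0). Zic2, a zinc finger factor of granule cells (0.92, 0.81 to 1.04), Cntn2, the axonal adhesion molecule TAG-1 (0.66, 0.49 to 0.83), Btg2, an antiproliferative factor (0.42), and Neurod1, the proneural factor of granule neurons (371 and 463 CPM, 0.32, 0.28 to 0.36), led it. In synaptic and neuronal maturation 14 of 19 members were higher, with a median of 0.19 (percentile 99.6), among them Syn2 (0.52), Nrxn3 (0.39) and Gria4 (0.22). The differentiation median was 0.07 with TMM factors, 0.05 among female and 0.28 among male cells, and the synaptic median was 0.05 among female cells. Counts of higher members and list medians stand beside a median over all genes that was not 0. It was 0.06 in progenitor-like, 0.03 in granule neuron-like, -0.01 in Purkinje cell-like and 0.06 in astroglia-like cells. Cytosolic ribosomal proteins had 70 of 83 members lower, and their median of -0.19 lay below all 10000 random lists. Rplp0 (-0.47), Rps2 (-0.46), Rps9 (-0.40) and Rpl3 (-0.40) led it, while 11 members had an interval above 0, such as Rps29 (0.58), Rps28 (0.55) and Rpl38 (0.51). The sex-linked list had a median of 0.26 (percentile 99.2), with Uty (0.34), Tsix (0.29), Kdm5d (0.35) and Eif2s3y (0.22) higher, Ddx3y at 0.15 and Xist at -0.23, beside the larger share of male cells in the mutant library, and its median was -0.02 among male cells.

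In the pathway of Sonic hedgehog, the main mitogen of granule cell progenitors, 16 of 18 members were higher, with a median of 0.16 at percentile 97.2 that was 0.09 with TMM factors. Of its members, Gli1 stood at 29.0 and 29.4 CPM (0.02, -0.13 to 0.18), Ptch1 at 0.08 and Mycn at 0.00 (-0.07 to 0.08). Ccnd1 (0.18) and Ccnd2 (0.19), the D-type cyclins, Sfrp1 (0.64), Atoh1, the progenitors' defining transcription factor (68.3 and 77.7 CPM, 0.19), were higher, as was Mki67 (0.24), a member of the G2/M list. The S phase list had 21 members higher and 21 lower (percentile 2.89), and the G2/M phase list had 37 of 51 higher with a median of 0.09 (percentile 90.5). Migration and axon guidance had a median of 0.13 (percentile 95.5), the Notch pathway -0.04 (percentile 7.25), Wnt pathway targets 0.08 (percentile 62.8), and Purkinje cell maturation and zones 0.13 (percentile 88.4). Hypoxia and glycolysis had -0.05 (percentile 6.79), interferon response 0.15 over 5 members (percentile 65.4), and mitochondrially encoded genes -0.08 (percentile 15.1). BMP and TGF-beta targets at 0.01 (percentile 27.3), immediate early and dissociation genes at 0.04 (percentile 40.6) and p53 and apoptosis at 0.03 (percentile 28.7) took the opposite sign with either TMM or DESeq2 factors.

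**Figure D4:**
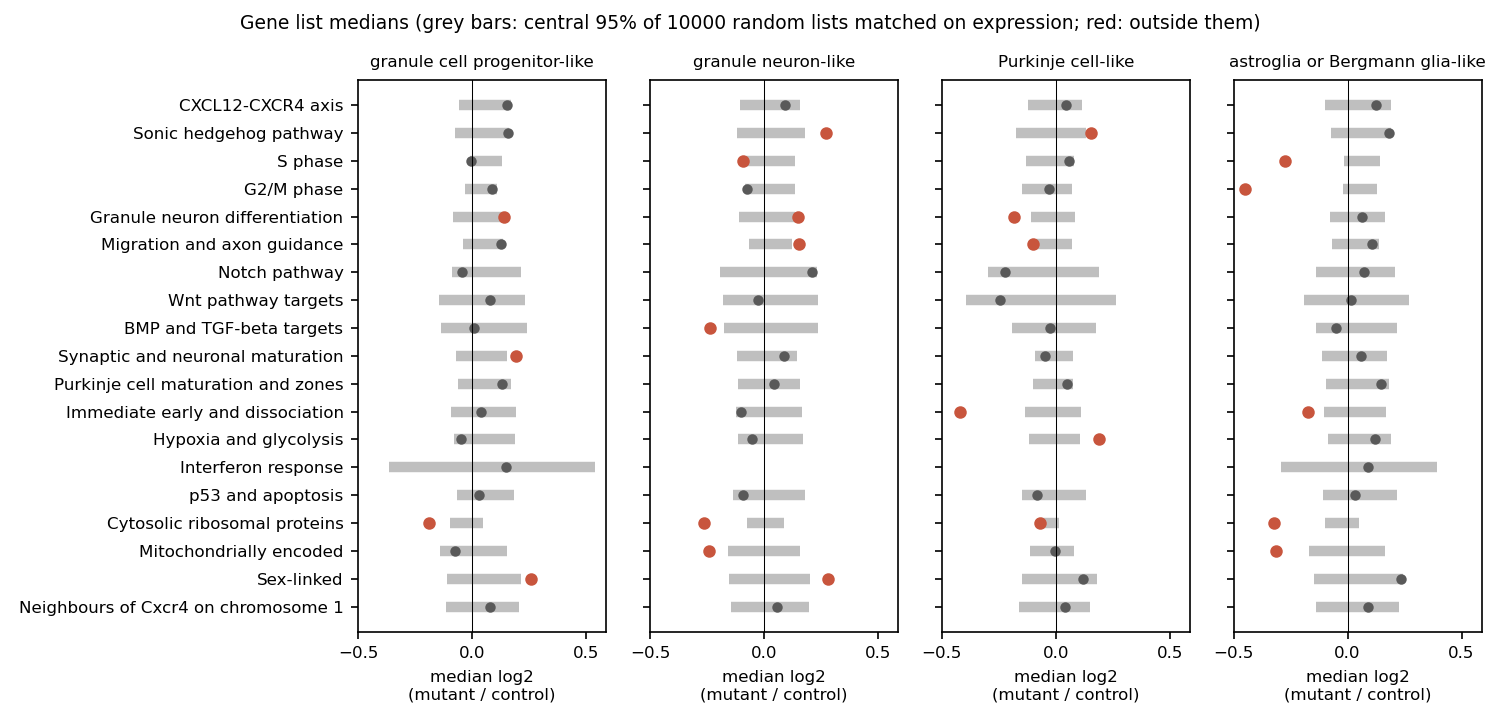
Median log2 ratio of mutant to control (x axis) for each gene list (y axis) in the 4 main classes, with grey bars for the central 95% of 10000 random lists and red points for medians outside them. Ribosomal proteins lay at -0.19 in progenitor-like and -0.32 in astroglia-like cells, and G2/M phase genes at -0.45 in astroglia-like cells.

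Granule neuron-like cells of the mutant library showed higher medians of the migration, differentiation and hedgehog lists, and lower medians of the ribosomal, mitochondrial and S phase lists. Of 12618 genes, 344 were at least 1.5-fold higher and 215 lower. This split moved from 61.5% higher to 53.2% with TMM factors (298 and 262) and to 53.8% with DESeq2 factors (301 and 259). Jund (117 and 373 CPM, log2 ratio 1.67), Sft2d3 (1.80), Dapk3 (1.73), Tmem158 (1.47), Suds3, of the Sin3 corepressor complex (1.43), Frat2, a Wnt pathway component (1.47), Slc7a3, a cationic amino acid transporter (2.42, 1.19 to 3.94), and Aard (2.03) ranked highest. Cyp26b1, which degrades retinoic acid (-1.63, -2.16 to -1.13), Apoe (-1.37), Sparcl1 (-1.26), Ednrb (-1.45), Calb2 (-1.35, with 36.4% of its control UMIs in 1 cell), Id4 (-1.52) and Aqp4 (-1.62) were among the lowest, at 0.253% to 1.33% of their level in the class with most of them. Migration and axon guidance had 23 of 32 members higher, with a median of 0.15 (percentile 99.6), led by Siah1a, which controls exit from the germinal zone (0.52), the netrin receptor gene Dcc (0.35, 0.32 to 0.38), Robo1 (0.37) and Ntn1 (0.56). Granule neuron differentiation had 17 of 23 higher (median 0.15, percentile 98.9), with Zic2 (0.81), Btg2 (0.37), Nfia (0.28) and Neurod1 (0.27). The Sonic hedgehog pathway had 13 of 14 higher (median 0.27, percentile 99.9), with Sfrp1 (0.65), Smo (0.31), Cdon (0.67) and Boc (0.23), each at 6.93% to 30.5% of its highest class. The median of this list was 0.15 among female cells.

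Lower lists in granule neuron-like cells were ribosomal proteins, with 72 of 83 members lower and a median of -0.26 below all random lists, and mitochondrially encoded genes, with 11 of 13 lower and a median of -0.24 (percentile 0.045). Rplp0 (-0.49), Rps2 (-0.47), Rpl3 (-0.47) and Rpl22l1 (-0.47) led the former and mt-Cytb (-0.37), mt-Atp6 (-0.28), mt-Co2 (-0.27) and mt-Nd5 (-0.29) the latter. Both lists split, since 9 ribosomal members had an interval above 0, among them Rps29 (0.50), Rps28 (0.48), Rpl38 (0.45), Rps27 (0.39) and Rps21 (0.34), and mt-Nd3 stood at 0.40. S phase genes had a median of -0.09 (percentile 1.63), with Pcna (-0.28), Mcm2 (-0.52), Slbp (-0.20) and Mcm6 (-0.46), and the median was -0.04 with predicted doublets kept and -0.01 among genes with at least 200 UMIs. BMP and TGF-beta targets had a median of -0.24 over 8 members (percentile 0.55), with Id4 (-1.52), Atf3 (-1.88), Id3 (-0.64) and Bambi (-0.29, -0.84 to 0.26), and a median of 0.04 among male cells and -0.01 among genes with at least 200 UMIs. The sex-linked list had a median of 0.28 (percentile 99.8), with Uty (0.64), Eif2s3y (0.46), Ddx3y (0.29) and Kdm5d (0.28), and a median of 0.00 among male cells. Mki67 (-0.62, -1.06 to -0.17) was lower, and Ccnd1 (0.14, -0.07 to 0.35), Ptch1 (0.09, -0.01 to 0.20) and Atoh1 (0.41, -0.25 to 1.10) were not separated from 0.

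In Purkinje cell-like cells of the mutant library the immediate early median was lower and the glycolysis median higher, but the former was -0.02 under the stricter filter and the latter 0.04 among female cells. Shh, the mitogen these cells supply to granule cell progenitors, stood at 21.4 and 21.5 CPM (0.00, -0.22 to 0.23). Of 12967 genes, 281 were at least 1.5-fold higher and 417 lower. Tmem158 (log2 ratio 1.87), Jund (69.2 and 225 CPM, 1.70), Dapk3 (1.96), H1fx, a linker histone (1.70), Hras (1.54, 1.39 to 1.69), Nsmce4a, of the SMC5/6 complex (1.55), Taf10 (1.55) and Itpka, a kinase of inositol trisphosphate (46.1 and 125 CPM, 1.44), ranked highest, and Hras and Itpka had their highest level in this class. Lpar1 (-3.07, -4.03 to -2.24), Grp (-2.59, with 72% of its control UMIs in 1 cell), Tnc (-2.01), Cdh8 (-1.68), Slit3 (-1.98), Egfr (-2.02), Grm8 (-1.71) and Atf3 (-2.11) ranked lowest, at 0.287% to 7.55% of their level in the class with most of them. Immediate early and dissociation genes had 14 of 17 members lower, and their median of -0.42 lay below all random lists, with Atf3, Junb (-0.79), Klf6 (-0.74) and Egr1 (-0.72), against the higher Jund, also a member. Hypoxia and glycolysis had 13 of 15 higher (median 0.19, percentile 99.9), with Pdk1 (0.63), Hk2 (1.52, 0.30 to 2.89), Bnip3 (0.41) and Eno1 (0.27).

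The Sonic hedgehog list had 13 of 16 members higher in Purkinje cell-like cells (median 0.16, percentile 98.8), with Ccnd2 (0.61), Sfrp1 (0.77), Boc (0.25) and Ptch1 (0.26), each at 1.27% to 24.3% of its highest class. Migration and axon guidance had 24 of 31 lower (median -0.10, percentile 0.95), with Ntrk2 (-1.30), Nrp2 (-1.06), Plxna2 (-1.38) and Slit2 (-0.49, 282 and 200 CPM), and Slit2, a guidance ligand, had its highest level in this class. Granule neuron differentiation had 15 of 22 lower (median -0.18, percentile 0.03), with Grin2b (-0.88), Btg2 (-0.72), Klf4 (-0.67) and Chd7 (-0.34), and ribosomal proteins 58 of 83 lower (median -0.07, percentile 1.35), with Rps2 (-0.34), Rplp0 (-0.32), Rpl11 (-0.24) and Rpl3 (-0.23), while 20 had an interval above 0, up to Rps29 (0.65). Purkinje cell maturation and zones had 14 of 20 higher (median 0.05, percentile 93.6). Mitochondrial UMIs made up 7.43% and 7.44% of these cells. Under the stricter filter, which asked for at least 1000 genes and at most 5% mitochondrial UMIs at once, the ribosomal median was 0.20, the differentiation median 0.06, the migration median -0.41, the hedgehog median 0.60 and the glycolysis median 0.36. With genes that have most of their RNA in another class left out, the differentiation median was 0.07, the immediate early median -0.12 and the hedgehog median 0.04.

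Astroglia-like cells of the mutant library, taken as a class, had lower cell cycle transcripts and lower Hes5. The G2/M list had 47 of 51 members lower, 42 with an interval below 0, with a median of -0.45, and the S phase list had 36 of 42 lower with a median of -0.28, both below all random lists. Ube2c (-0.90, -1.03 to -0.76), Birc5 (-0.82), Hmmr (-0.91) and Cenpf (-0.59) led the former and E2f8 (-0.75), Rrm2 (-0.49), Tipin (-0.43) and Prim1 (-0.55) the latter. Thinned to 2000 UMIs, 13.5% of control and 8.78% of mutant astroglia-like cells had a Mki67 UMI. Cluster 26 of this class, with Prc1, Ckap2 and Aspm among its leading genes, held 122 of 751 control and 46 of 469 mutant cells. These class values do not tell a smaller share of dividing cells from lower transcripts within cells. Hes5 (ENSMUSG00000048001, chromosome 4, 154960923 to 154962371), which Notch signalling induces in glia and progenitors, stood at 581 and 312 CPM (-0.90, -0.97 to -0.83) in the class that has most of it. The G2/M median was -0.20 with predicted doublets kept and -0.84 with doublet removal doubled, and the S phase median was -0.44 among female cells.

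Of 13018 genes in astroglia-like cells, 500 were at least 1.5-fold higher and 292 lower, a split that moved from 63.1% higher to 49.1% with TMM factors (366 and 380) and to 49.1% with DESeq2 factors. Sft2d3 (2.49), C2cd4b (2.62), Aard (2.05), Prr7 (1.96), Jund (108 and 371 CPM, 1.78), Tmem158 (2.08), Dapk3 (1.96) and Suds3 (1.41) ranked highest. Besides Hes5 and Ube2c, Ndst4 (-2.51), Rasd1 (-2.06), Hist1h2af (-1.54), Htr2a (-1.81), Ppp2r2c (-1.23) and Maff (-1.04) ranked lowest, and Ndst4, with 38% of its control UMIs in 1 cell, stood at 0.519% of its level in cells with markers of cerebellar nuclei. Immediate early genes had 14 of 18 lower (median -0.17, percentile 0.14), with Klf6 (-0.52), Socs3 (-0.56), Junb (-0.43) and Atf3 (-0.48). Ribosomal proteins had 70 of 83 lower with a median of -0.32 below all random lists, with Rplp0 (-0.58), Rps2 (-0.56), Rps9 (-0.47) and Rpl19 (-0.46), while 8 had an interval above 0, up to Rpl38 (0.42). Mitochondrially encoded genes had 11 of 13 lower (median -0.31, percentile 0.01), with mt-Cytb (-0.51), mt-Atp6 (-0.43), mt-Co2 (-0.40) and mt-Co1 (-0.33) against mt-Nd3 at 0.37, and a median of -0.20 over all deposited barcodes. Mycn (0.57) and Ptch1 (0.24) were higher and Ccnd2 (-0.23) was lower.

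A group of 52 genes was at least 1.5-fold higher in the mutant library in all 4 main classes, among 10746 genes measured in each. Hes5 was the only gene lower by that size in all 4, but stood at 0.893%, 0.578% and 0.411% of its astroglia-like level in progenitor-like, granule neuron-like and Purkinje cell-like cells. The 52 genes were also higher, by any size, in female and in male cells, and their median log2 ratio ran from 0.69 in ependymal-like to 1.03 in oligodendrocyte lineage-like cells over the 10 classes measured. Sfrp1, named above as a member of the Sonic hedgehog list, was among the 52, at 0.64 to 0.77 over the 4 main classes. Dapk3 and Jund (ENSMUSG00000071076, chromosome 8, 70698949 to 70700616) had the largest lowest ratio of the 4 classes, at 2.70 and 10.8 and at 93.6 and 311 CPM of the whole library. The median GC content of the 52 genes was 55.2%, against 49.9% for the genes tested, and 11.5% of them had 1 exon, as Jund does, against 2.31%.

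**Figure D5:**
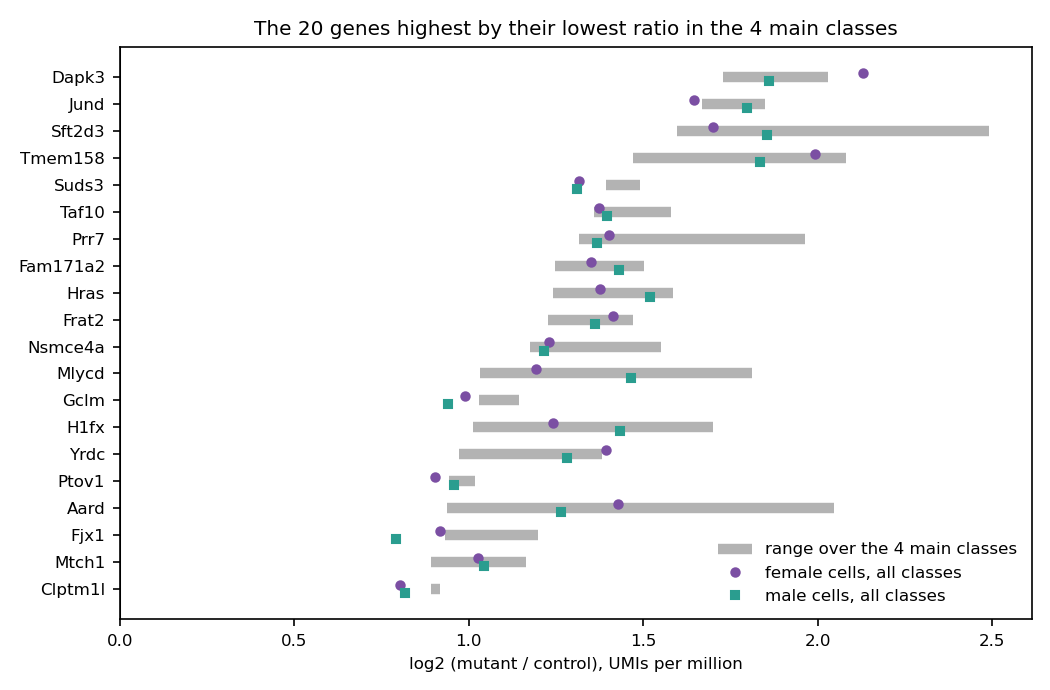
Log2 ratio of mutant to control (x axis) for the 20 genes with the highest lowest ratio over the 4 main classes (y axis), with grey bars for the range over these classes, circles for female cells and squares for male cells. Jund lay between 1.67 and 1.85 over the classes, at 1.64 in female and 1.80 in male cells.

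Over the whole library, 422 of 19111 genes were at least 1.5-fold higher and 1414 lower in the mutant library, a sum that follows the shares of the classes as well as their transcripts. Neurod1 was higher at 235 and 349 CPM (log2 ratio 0.57), and C1ql1 (4.03-fold), Tmem158 (3.74-fold), Dapk3 (4.01-fold), Jund (3.33-fold) and Sft2d3 (3.48-fold) ranked among the highest. Phox2a, Slc6a2 and Dbh, genes of noradrenergic neurons, ranked high from 1 mutant cell with 85, 165 and 62 of their UMIs. The lowest genes were neutrophil transcripts, S100a9 (3287 and 4 UMIs, 37.02% of the former in 1 cell), S100a8 (2400 and 12), Cstdc5 (636 and 1), Cstdc4 (579 and 1), Stfa2 (301 and 1), Retnlg (279 and 1) and Stfa1 (1062 and 3, log2 ratio -8.60, -10.88 to -7.05), and Stfa2l1 (389 and 0) was at least 142-fold lower. Interferon response genes had 14 of 15 members lower (median -0.80, below all random lists) and BMP and TGF-beta targets 9 of 12 (median -0.55). Immediate early genes had 15 of 18 lower (median -0.47), and the Notch pathway 9 of 13 (median -0.31, percentile 0.01). Granule neuron differentiation had 21 of 23 higher (median 0.21, percentile 99.97), synaptic and neuronal maturation 17 of 19 (median 0.19) and the Sonic hedgehog pathway 14 of 18 (median 0.18). Wnt pathway targets had 9 of 12 lower (median -0.23, percentile 1.40).

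Shares of cells with a marker UMI, which need no clusters, were higher in the mutant library for markers of granule neurons and interneurons and lower for endothelium. Neurod1 was found in 27.6% of control and 35.8% of mutant cells at 2000 UMIs (46.3% and 59.9% without thinning), against 1.87% and 1.28% of astroglia-like cells, whose median depths were 13803 and 14657 UMIs. Pax2, of GABAergic interneuron precursors, was found in 10.4% and 14.01% (16.8% and 22.9%), against 0.686% and 0.478% of progenitor-like cells. Pax6, of the granule lineage, was found in 20.4% and 25.2% (45.3% and 53.2%), against 1.61% and 0.234% of Purkinje cell-like cells. Atoh1 was found in 2.62% and 2.99% (10.1% and 12.7%), against 0 of 497 and 0 of 428 Purkinje cell-like cells, which allows up to 0.604% and 0.701%. Calb1, of Purkinje cells, was found in 12.2% and 10.9% (27.5% and 27.9%), against 4.20% and 3.41% of progenitor-like cells. Foxp2 was found in 20.1% and 20.8% (41.4% and 42.3%), against 1.80% and 2.26% of granule neuron-like cells, and at 4000 UMIs the difference was -0.641 points in the single draw and -0.288 on average. Cldn5, of endothelium, was found in 1.44% and 0.759% (3.72% and 2.26%), Olig1, of the oligodendrocyte lineage, in 2.54% and 2.04% (4.03% and 3.50%), and C1qa, of microglia, in 0.785% and 0.635% (1.17% and 1.08%). Averaged over draws at 2000 UMIs, mutant minus control was 8.99 points for Neurod1, 3.60 for Pax2, 4.49 for Pax6, 0.521 for Atoh1, -1.26 for Calb1, 0.577 for Foxp2, -0.732 for Cldn5, -0.369 for Olig1 and -0.107 for C1qa. Among female and male cells the averages were 3.22 and -1.28 for Foxp2, -0.940 and 0.0834 for Olig1, -0.262 and 0.102 for C1qa and -0.0620 and 0.663 for Atoh1. At 4000 UMIs they were 2.06 and -1.83, -1.24 and 0.0384, -0.292 and -0.0162, and 0.0560 and 1.10 in this order. Opposite signs were found at both depths for Foxp2 and Olig1 only. The male Olig1 values lay within their standard deviations over draws, 0.193 and 0.175 points, so their sign was not established. In progenitor-like cells Cldn5, Olig1 and C1qa were found in 0.534% and 0.273%, in 0.229% and 0.0683%, and in 0.153% and 0 of 1465 cells.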

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

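The explanations below were tested after the results had been seen, apart from the test on genes without introns, which was set out before its result was seen.

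The share of cells with markers of cerebellar nuclei differed in opposite directions between the sexes, by 2.56 points among female cells and -2.74 points among male cells, and the difference between the sexes was not tested. Whether these cells are of the cerebellum or of midbrain at the edge of the dissection was not tested either. Cluster 23, an unnamed group outside the comparisons whose leading gene was Hbb-bs, held 2.06% of mutant cells, against 1.09% of control cells. Barcodes with under 500 genes, which were left out of the comparisons, were 7.60% of the mutant library (7.08% to 8.15%), against 4.25% of the control library (3.85% to 4.67%). Barcodes with over 10% mitochondrial UMIs, also left out, went the other way. They were 7.57% of the mutant library (7.05% to 8.12%), against 9.34% of the control library (8.76% to 9.94%).

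The first pattern was the group of 52 genes higher in the mutant library in all 4 main classes, with a median log2 ratio of 0.98 in progenitor-like cells. GC content of the transcripts was argued against, since the upper bound of the central 95% of random lists matched on GC and expression was 0.111. A lack of introns could not account for the group, since 6 of the 52 genes had 1 exon. The 464 other genes with 1 exon had a median of 0.0261, which argued against a shift of 1-exon genes in general. Free RNA from another class was not decided. The members stood at 45.1% or more of their highest class as a median in each of the 4 classes. They were chosen as measured and higher in each of these classes, and the level of the other tested genes was not set beside them. A single animal was argued against, since the lower of the medians for female and male cells was 0.873. Genotype and preparation of the library cannot be told apart, since each genotype has 1 library and the lowest median over 10 classes was 0.694. A difference of the whole library, in genotype or in handling, may therefore underlie these genes, Jund among them.

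The second pattern was the lower number of fibroblast-like, vascular and astroglia-like cells in the mutant library. The filter on barcodes was argued against as the whole cause for the fibroblast-like cells, whose difference was -1.59 points over all deposited barcodes, and a single animal was argued against for the fibroblast-like and astroglia-like cells, whose ratios had upper bounds of at most 0.328 and 0.741 in either sex. For the vascular cells a single animal was not excluded, since the upper bound reached 2.02, with 11 mural-like cells in each library among male cells. A loss of meninges with all their cells at dissection was not decided. From 26 control and 32 mutant cells, the border macrophage-like ratio had a lower bound of 0.724, above the interval of the fibroblast-like ratio. Among female cells its lower bound was 0.288, under the fibroblast-like upper bound of 0.321. Among male cells it was 0.466, above the fibroblast-like upper bound of 0.328. Whether the border macrophage-like cells came from the meninges was not tested. Genotype and preparation, such as the efficiency of dissociation, cannot be told apart with 1 library per genotype, and the fibroblast-like ratio of 0.198 may come from either.

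The third pattern was the lower progenitor share of the granule lineage in the mutant library. Low-depth cells with granule neuron markers are a candidate explanation, since the difference was 0.827 points once they were counted as granule neurons, and they numbered 341 in the control and 99 in the mutant library. Doublets were argued against, since keeping them or doubling their removal moved the difference by at most 0.407 points. A single animal was not excluded, since the smaller of the differences in female and male cells was -3.41 points with a counting error of 4.10 points, and genotype and preparation cannot be told apart behind the difference of -4.40 points.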

How the results depend on the processing

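The alternatives on cells of each sex, on low-depth clusters named by markers, on genes mostly in 1 cell and on the average over thinning draws were chosen after seeing the data. No paired analysis was possible because each genotype had 1 library. Among the values that answer a comparison, 423 stayed within their spread or within 1.5 times their count under the alternatives, 65 moved further and 4 turned direction. Among the others, 1323 stayed, 82 moved and 12 turned. The spread was the counting error or, for list medians, came from the range of random lists. Only values beyond their spread in the main setting could count as turned. Other changes of sign, such as that of Top2a, were counted as stayed or moved. All alternatives were run, and some lists had too few members for a value under some of them. Where no cause is named below, the cause was not tested.

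Differences in shares of cells, in points, moved as follows. With coarser clusters the granule neuron-like difference was 1.51 and the progenitor share of the lineage 1.02. With finer clusters the astroglia-like difference was -6.33. With low-depth clusters named by markers the granule neuron-like difference was 1.51, the astroglia-like one -6.65 and the progenitor share 0.827. With cells thinned before clustering, the values were 2.43 for granule neuron-like, 4.13 for GABAergic interneuron-like, -5.55 for astroglia-like and 0.283 for unnamed cells and -1.58 for the progenitor share. The astroglia-like difference was -7.14 over all deposited barcodes, -2.58 under the stricter filter and -6.56 with predicted doublets kept. With doublet removal doubled, the Purkinje-like difference was 0.271 and the fibroblast-like one -2.22. Among female cells the differences were -0.214 for progenitor-like, 2.02 for granule neuron-like, 2.56 for cerebellar nuclei and 3.61 for GABAergic interneuron-like cells. Among male cells they were 0.442 for progenitor-like, 6.22 for granule neuron-like and -5.80 for astroglia-like cells and -8.00 for the progenitor share.

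In progenitor-like cells, the summed S phase log2 ratio was -0.00944 with doublet removal doubled, and the summed G2/M ratio was 0.0572 under the stricter filter, 0.0536 with doublet removal doubled, 0.0860 in female and 0.0135 in male cells. In single thinning draws the Mki67 difference was 3.29 points with doublets kept, 1.23 at 4000 UMIs, 1.95 in female and 2.65 in male cells, and it was 2.35 without thinning. Averaged over draws it was 3.45 at 4000 UMIs and, at 2000 UMIs, 5.36 in female and 2.79 in male cells. Without thinning the Atoh1 difference was 2.53 points, the Neurod1 difference 13.6 and the Calb1 difference 0.443, where deeper cells bring more UMIs by construction.

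Counts of genes at the fold size follow the number of genes tested or the size asked for. Without a minimum count, 3744 genes were higher and 2922 lower in progenitor-like cells, 3621 and 2926 in granule neuron-like, 2966 and 4219 in Purkinje-like and 3825 and 3604 in astroglia-like cells, and 2596 and 4405 in the whole library. With at least 200 UMIs the counts were 186 and 26, 126 and 38, 113 and 91, 171 and 72, and 214 and 861 in the same order. At 2-fold they were 79 and 32, 69 and 35, 51 and 99, 78 and 43, and 86 and 452. In Purkinje-like cells 595 were higher under the stricter filter and 241 lower among female cells, with fewer cells in each.

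List medians and single genes moved as follows. In progenitor-like cells the G2/M median was 0.163 in female and 0.0170 in male cells, and in male cells the differentiation median was 0.284 and the sex-linked median -0.0158. In granule neuron-like male cells the BMP and TGF-beta median was 0.0354 and the Cxcl12 log2 ratio -0.0808. In Purkinje-like cells the differentiation median was 0.0570 under the stricter filter, 0.0729 with doublet removal doubled, 0.0702 without genes of other classes and 0.0187 in male cells, and the ribosomal median was 0.199 under the stricter filter. The Ackr3 log2 ratio in astroglia-like female cells was -0.149. Depth limits the small classes, where 33 mutant fibroblast-like cells fell under the 100 cells asked for. In simulated counts with counting error only, a 2-fold difference was recovered for 91.0% to 98.5% of the altered genes, and a 1.5-fold difference, which lies at the fold size itself, for 37.3% to 56.7%.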

Other observations

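The observations below, and the tests named with them, were chosen after the results had been seen.

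In 3 classes outside the main comparisons Jund was again among the 2 highest-ranked genes, with log2 ratios of 1.99 in unipolar brush cell or rhombic lip-like cells, 1.78 in GABAergic interneuron-like cells and 1.90 in GABAergic or glial progenitor-like cells, beside Tmem158 (2.10), Dapk3 (2.16) and Frat2 (1.97) in the same order. Hes5, an effector of Notch signalling that keeps progenitors undifferentiated, was lower in GABAergic or glial progenitor-like cells, at 349 and 170 CPM (-1.04, -1.17 to -0.91), and in ependymal-like cells (-1.64, at 5.31% of its astroglia-like level), as it was in astroglia-like cells. Arhgap6 (13.8 and 4.88 CPM) was the other low gene of the progenitor-like class. In ependymal-like cells Id3, a BMP target, was lower (-1.11), and Dcc (75.7 and 303 CPM) and Zfp804a (log2 ratio 3.17), at 1.90% and 1.84% of their highest class, were higher, but 37.6% and 49.3% of their mutant UMIs came from 1 cell. In unipolar brush cell-like cells Tfap2b (-3.22) and Nckap5 (-2.53) were lower, at 2.89% and 1.83% of their highest class, and in GABAergic interneuron-like cells Tcf7l2 (-1.63) and Id4 (-1.41), at 0.668% and 1.503%.

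In oligodendrocyte lineage-like cells the myelin gene Mobp was lower in the mutant library, but 92.9% of its control UMIs came from 1 cell. Mobp had 98 and 0 UMIs, at least 37.5-fold lower. Igfbpl1 (2.44) and Tfap2b (2.82) were higher, at 4.06% and 2.498% of their highest class. In cells with markers of cerebellar nuclei, Slc6a2 (0 and 165 UMIs, at least 57.9-fold higher) and Phox2a (0 and 85, at least 29.8-fold) came from 1 mutant cell, and Pkib (-3.51) and Hspa2 (-2.80) were lower, at 4.22% and 2.45% of their highest class. The sex-linked list of that class had a median of -1.25, below all random lists, beside its lower share among male cells. Cluster 13, with midbrain-like leading genes, held 4.02% and 4.53% of female cells and 2.30% and 0.632% of male cells, lower among male cells as the class with markers of cerebellar nuclei was.

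G2/M phase genes were also lower in GABAergic or glial progenitor-like cells, with 43 of 51 members lower and a median of -0.16, and in oligodendrocyte lineage-like cells, with 39 of 51 lower and a median of -0.20, while in ependymal-like cells 43 of 50 were higher and the median was 0.17. Ribosomal proteins had a negative median in each of the 10 classes, from -0.07 in Purkinje-like to -0.32 in astroglia-like cells, although the Purkinje-like median was 0.20 under the stricter filter.

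Granulocyte-like cells with at least 10 UMIs of S100a8 and S100a9 numbered 9 among retained control cells of the lymphocyte or granulocyte-like class, 0.117% of the library (0.0534% to 0.221%), with 1 further control cell in another class, and 0 of 7568 mutant cells of any class, which allows a share of up to 0.0396%. Among all deposited barcodes there were 12 in the control and 3 in the mutant library. Haemoglobin transcripts stood at 12.1 CPM in the control and 42.3 CPM in the mutant library, a ratio of 3.48 (3.27 to 3.71), and at 9.93 and 32.2 CPM without cluster 23. Malat1 made up 2.17% and 2.89% of UMIs in cluster 14 and 1.77% and 4.34% in cluster 19, against 1.15% and 1.36% in granule neuron-like and 1.60% and 1.96% in astroglia-like cells.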
